A study of Homo sapiens with 9 samples.

How the data were processed

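The deposited values are log2 expression per probe set, made by the authors with robust multi-array averaging (RMA) per the submitters' processing notes. The software, its version and the chip description file are not given in the sources used here. RNA was extracted with a 96-well column kit and labelled with biotin by the standard Affymetrix protocol, per the labels. The 9 arrays, of 54675 probe sets each, form 3 groups of 3: DMSO, 100 nM angiotensin II and 100 nM torcetrapib, all at 3 h. Values ran from 2.50 to 14.6. The series design text calls angiotensin II a CETP inhibitor, which the sample labels do not, and that wording was not used. Serial numbers in the sample titles run without a gap within each group, so any order of processing cannot be told apart from treatment.

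No further normalisation was applied. The 62 control probe sets were left out of the gene tests, and 41091 probe sets carried 1 gene symbol, 1801 several and 11721 none. Probe sets with several symbols or none were not tested. Each of the 19775 genes was represented by its probe set with the highest mean over all 9 arrays, which did not depend on group, and 10523 genes had more than 1 to choose from. Symbols were matched to the current gene table, names only.

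Differences were tested with limma 3.58.1 in R 4.3.3. One linear model with 3 group means was fitted to all genes, which left 6 residual degrees of freedom, and variances were moderated with an intensity trend. P-values are two-sided, adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Intervals are 95% and unadjusted. A change written ± carries a standard error (SE), a level written ± a standard deviation (SD, n = 3).

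The 17 gene lists were fixed from general knowledge before the data were examined, and 294 of their 323 members were measured, the other 29 being not analysed here. They are steroidogenesis, immediate early transcription factors, MAP kinase and G protein feedback regulators, cAMP and CREB targets, calcium signalling with pumps and channels, RAAS components, cholesterol synthesis, cholesterol uptake with storage and efflux, zona glomerulosa and WNT markers, ER stress and unfolded protein response, heat shock, oxidative stress and xenobiotic response, secreted growth factors and cytokines, circadian clock, cell cycle, adrenal medulla markers, and fibroblast, endothelial and immune markers. Shifts of lists were tested with camera at its preset correlation between genes, adjusted over all 51 list tests, and again with an estimated correlation and with fry. Counts called adjusted over the list alone use the adjustment within that list.

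The 5′ to 3′ index of each array is the mean over ACTB and GAPDH of the 5′ minus the 3′ control probe set, a choice of control genes settled after results had been seen. It was compared between groups by an exact two-sided permutation test. Alternatives tried were variance moderation without the trend or robust, a filter on dim genes, arrays centred or quantile normalised again, the mean of probe sets, all probe sets, no _x_at and _s_at probe sets, array weights, only the 2 groups compared, other thresholds, each array left out and the index as a covariate. The relation of both treatments was set beside 100 simulations of unchanged groups that share the DMSO arrays. In a self-test with known changes put into simulated values, the angiotensin II comparison found 15 of 50 genes changed 1.2-fold, 49 of 50 changed 1.5-fold and all 50 at 2-fold and at 4-fold, with 11 false among 175 calls. The torcetrapib comparison found 11 of 50 at 1.2-fold and all 50 at each of the other folds, with 13 false among 174 calls. That self-test assumes independent, normal noise.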

Results

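Gene expression was measured in H295R cells, a human adrenocortical carcinoma line that makes steroid hormones, after 3 h with DMSO as the vehicle, with 100 nM angiotensin II or with 100 nM torcetrapib. Angiotensin II is the peptide hormone of the renin-angiotensin-aldosterone system (RAAS) that drives aldosterone secretion from the adrenal cortex. Torcetrapib is an inhibitor of the cholesteryl ester transfer protein (CETP). The study asked whether such inhibitors switch on RAAS signalling in cells of adrenal origin, and whether a transcriptional response bears on blood pressure. Each of the 3 groups held 3 arrays, and their number limits the precision of every value. The deposited values are log2 expression per probe set after robust multi-array averaging (RMA), and 19775 genes were compared, each by its brightest probe set. The median probe set of an array lay between 5.539 and 5.605. Arrays of one group correlated with r from 0.9964 to 0.9985 across genes, which are not independent replicates, and arrays of different groups with r from 0.9933 to 0.9977. The first principal component held 43.9% of the variance, with the angiotensin II arrays between 18.3 and 21.4 and the other 6 arrays between -12.8 and -6.50. The labels do not say that the arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

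A sign of RNA quality was higher on the torcetrapib arrays. This index was the log2 signal of the 5′ minus the 3′ control probe sets, averaged over ACTB and GAPDH. It was -0.50 ± 0.22 (SD, n = 3) with DMSO, -0.62 ± 0.02 with angiotensin II and -0.24 ± 0.03 with torcetrapib. All 3 torcetrapib arrays lay above the other 6, and a two-sided exact permutation test gave p = 0.1 against each of the other groups, which is the smallest p that 3 against 3 arrays allow. The same permutation test gave p = 0.5 between angiotensin II and DMSO. DMSO replicate 2, at -0.2758, lay next to torcetrapib replicate 1, at -0.2751.

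**Figure D1:**
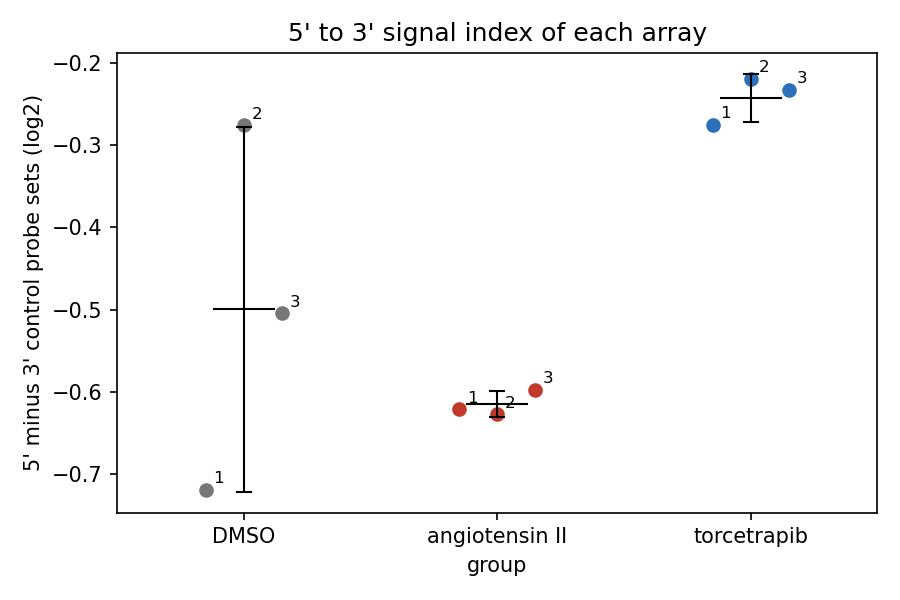
The 5′ minus 3′ index of each array (vertical axis, log2 units) by group, with 1 point per array, a line for the group mean and whiskers for the SD. The torcetrapib arrays, between -0.2751 and -0.2193, lie above every angiotensin II array and above the DMSO arrays, of which replicate 2 is at -0.2758.

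Angiotensin II against DMSO shows what the RAAS hormone itself did to these cells within 3 h. The largest rises were of transcription factors and signalling proteins that many cells switch on within hours of a stimulus. NPAS4, an activity-dependent transcription factor, rose 35.5-fold, from 5.20 ± 0.24 (SD, n = 3) to 10.35 ± 0.21 on the log2 scale. The orphan nuclear receptor NR4A2 rose 28.8-fold, from 6.25 ± 0.25 to 11.10 ± 0.04, and its relatives NR4A3 and NR4A1 rose 7.81-fold and 6.66-fold. The largest fall was of TXNIP, a thioredoxin-binding protein that limits glucose uptake, which ended 3.72-fold lower.

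With limma and Benjamini-Hochberg adjustment over all genes, 665 genes rose and 545 fell with angiotensin II, 1210 in all, and 3259 passed an unadjusted p of 0.05. The balance turned without DMSO replicate 2 (550 higher, 594 lower), without angiotensin II replicate 3 (540 and 631) and with array weights (1342 and 1370). Those weights put angiotensin II replicate 1 at 6.15, against 0.448 and 0.480 for replicates 2 and 3. Of the 1210, 1199 had 3 treated arrays all on one side of the 3 DMSO arrays, as did 17.6% of all genes, where chance gives 10%. At least 2-fold changes numbered 113 rises and 12 falls. NPAS4 (log2 change 5.15 ± 0.14 SE, adjusted p = 9.08e-13) and NR4A2 (4.85 ± 0.10, adjusted p = 2.41e-14) led the rises. GEM, a small GTPase that restrains voltage-gated calcium channels, followed with a log2 change of 4.21 ± 0.06. FOSB and ATF3, partners in AP-1 type transcription factor dimers, rose by 3.86 ± 0.12 and 3.77 ± 0.07. NFKBIZ, a nuclear regulator of NF-kappa-B, rose by 3.64 ± 0.08, TAC1, the precursor of substance P, by 3.52 ± 0.17, the pseudokinase TRIB1 by 3.34 ± 0.06, NR4A3 by 2.97 ± 0.05 and the transcription factor MITF by 2.94 ± 0.05. TAC1 started at 4.11, dim against a median gene at 6.73, so the size of its rise is less certain than the others. After TXNIP, which fell by 1.89 on the log2 scale, the zinc finger gene ZNF658 fell by 1.78 and DUSP6, a phosphatase of the kinase ERK, fell by 1.75. The Notch target HES1 fell by 1.35, GTF2H2B fell by 1.33, the interferon-induced gene IFIT2 fell by 1.30 and the transcription factor GATA3 fell by 1.23. BBS12 fell by 1.21, DDIT4L, a regulator of mTOR signalling, fell by 1.11 and ZNF627 fell by 1.08. Probe sets that can bind several transcripts (types _x_at and _s_at) carry some of these values. Without them the calls of NR4A1, ZNF627 and HES1 ended, and HES1 turned in sign (adjusted p = 0.0796, 0.999 and 0.866, with lowest values over their alternatives of 3.07e-18, 4.84e-10 and 1.35e-10). A second _x_at probe set of NR4A1 changed by 2.23, and a second _s_at probe set of HES1 by -1.23. The probe sets left without these types were dimmer, with means of 6.88 for NR4A1 and 5.23 for HES1, against 11.9 and 8.70 for the brightest. NR4A2 has no other type of probe set: its 3 gave log2 changes from 4.85 to 5.22.

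**Figure D2:**
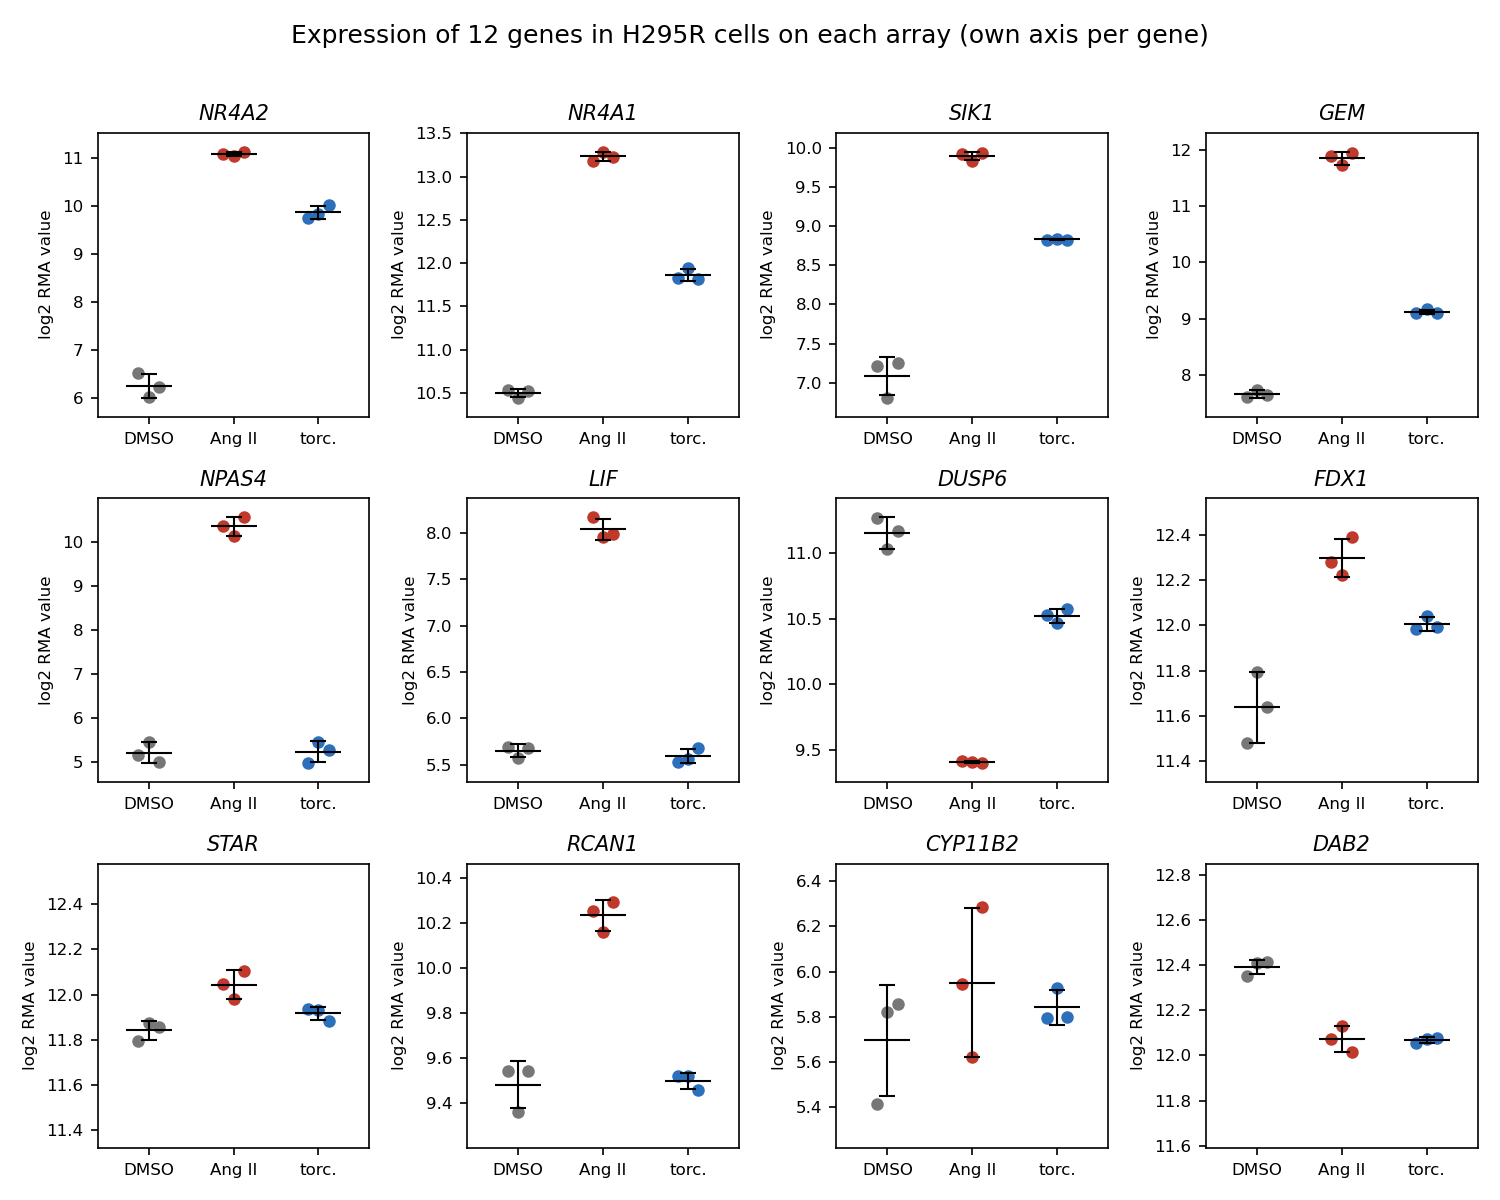
Expression of 12 genes on each array (vertical axes, log2 RMA value, own range per gene) by group, with 1 point per array, a line for the group mean and whiskers for the SD. NPAS4 is near 5.20 with DMSO and torcetrapib and 10.35 with angiotensin II, while NR4A2 is at 6.25, 11.10 and 9.88 with DMSO, angiotensin II and torcetrapib.

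The immediate early transcription factors rose almost as a whole with angiotensin II. Of 23 measured members 22 rose, both over all genes and adjusted over the list alone (camera adjusted p = 5.38e-75). FOS rose by 2.82, CSRNP1 by 2.19 and EGR1 by 1.21 on the log2 scale, while MYC had a change of -0.22 (adjusted p = 0.0749) that passed when adjusted over the list alone. Among cAMP and CREB targets 11 of 15 rose, and 11 when adjusted over the list alone (camera adjusted p = 5.46e-36). They included SIK1, a kinase that feeds back on CREB coactivators, with 2.81 ± 0.09, CITED2 with 1.91 and the phosphodiesterase PDE4B with 1.39. Among regulators of MAP kinase and G protein feedback 8 of 19 rose and 1 fell, and 9 and 2 when adjusted over the list alone (camera adjusted p = 8.71e-10). The mRNA-destabilising protein ZFP36 rose by 2.25, ERRFI1, an inhibitor of EGF receptors, by 1.73 and the phosphatase DUSP1 by 1.33, and DUSP6 was the fall. Secreted growth factors and cytokines rose in 8 of 23 cases, and in 10 when adjusted over the list alone (camera adjusted p = 2.95e-14). The matricellular protein CCN1 rose by 2.32 ± 0.04, HBEGF by 2.58 ± 0.09, LIF by 2.39 ± 0.09 and the chemokine CXCL2 by 2.54 ± 0.17, the last from a dim 4.22 with DMSO and with a value of -0.0235 when its _x_at probe set was left out. With an estimated correlation between genes the camera adjusted p of these lists, in the same order, were 0.00348, 0.00434, 0.0299 and 0.0253.

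Of 15 measured steroidogenesis genes 3 rose with angiotensin II and none fell, over all genes and adjusted over the list alone. FDX1, the ferredoxin that passes electrons to mitochondrial steroid hydroxylases, rose 1.58-fold (log2 change 0.66 ± 0.06, adjusted p = 2.58e-06). STAR, which carries cholesterol into mitochondria, rose 1.15-fold (0.20 ± 0.04, adjusted p = 0.00304). The corticotropin receptor MC2R rose 1.33-fold (0.41 ± 0.10, adjusted p = 0.0203). CYP11B2, aldosterone synthase, did not pass, with a log2 change of 0.25 and a 95% interval from -0.07 to 0.58 (limma adjusted p over its alternatives from 0.0431 to 0.823). With DMSO it lay at 5.70, under the median gene at 6.73, and CYP11B1 was dim at 4.36, under the lowest-quarter limit of 4.87. CYP11A1 (0.02 ± 0.04), CYP11B1 (0.07 ± 0.09), CYP17A1 (0.09 ± 0.06) and HSD3B2 (-0.12 ± 0.06) did not pass either. The camera test did not pass for the list (adjusted p = 0.0872), while it passed upwards without DMSO replicate 3 (0.0441) and with the 5′ to 3′ index in the model (0.0249, range 0.0249 to 0.465). The STAR call ended without the intensity trend in the variance (adjusted p = 0.0891, range over its alternatives 3.69e-05 to 0.0891), and the MC2R call without DMSO replicate 3, angiotensin II replicate 2 or replicate 3 (adjusted p = 0.0853, 0.0586 and 0.0727, range 0.0131 to 0.0853).

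Among components of the RAAS itself 0 of 11 rose and 2 fell, the same when adjusted over the list alone (limma, 0 and 2 at an unadjusted p of 0.05, camera adjusted p = 0.0709). The list passed downwards without DMSO replicate 3 or angiotensin II replicate 2 (adjusted p = 0.0401 and 0.0415, range 0.0107 to 0.490). The angiotensin receptor AGTR1 ended 1.25-fold lower (log2 change -0.32 ± 0.04, adjusted p = 0.000124), and the prorenin receptor ATP6AP2 1.17-fold lower (-0.22 ± 0.04), a call that ended with the mean of all its probe sets (adjusted p = 0.157, range 0.00066 to 0.157). Markers of the zona glomerulosa and of WNT signalling were shifted downwards: 0 of 16 rose and 5 fell, and 8 fell when adjusted over the list alone (camera adjusted p = 0.000466). DAB2, a glomerulosa marker, changed by -0.32 ± 0.03 and AXIN2, a WNT target, by -0.27 ± 0.05, the latter without a call by the mean of its probe sets (adjusted p = 0.0904, range 2.56e-05 to 0.0904). Among calcium signalling genes, pumps and channels 3 of 29 rose and 1 fell, and 4 and 2 when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.313). RCAN1, a calcineurin target and inhibitor, rose by 0.75 ± 0.06 and the transcription factor NFATC2 by 0.86 ± 0.09, while the fall was of the calcium release channel ITPR2. The RCAN1 call rests on an _s_at probe set: without that type its change was 0.279 (adjusted p = 0.278, range 1.96e-09 to 0.278).

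Stress lists rose in part with angiotensin II. Of 20 genes of ER stress and the unfolded protein response 8 rose, and 9 when adjusted over the list alone (camera adjusted p = 1.29e-08), with PPP1R15A at 1.80 ± 0.07, DDIT3 at 0.84 ± 0.06 and DNAJB9 at 0.57 ± 0.06. That call was lost with an estimated correlation between genes (adjusted p = 0.178, range over the alternatives 8.14e-11 to 0.178). In that list the chaperones HSPA5 and CALR did not pass the test. Of 9 heat shock genes 2 rose, with 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0058). DNAJB1 rose by 0.76 ± 0.06. That list lost its call too (adjusted p = 0.0917 with an estimated correlation, range 0.000702 to 0.0917). Of 18 oxidative stress and xenobiotic response genes 5 rose, and 9 when adjusted over the list alone (camera adjusted p = 1.62e-07), led by TIPARP with 1.97 ± 0.06. SRXN1 (0.35 ± 0.04) and SLC7A11 (0.36 ± 0.05), both targets of NRF2, rose as well.

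The other lists did not pass the camera test with angiotensin II (adjusted p from 0.0543 for the cell cycle to 0.765 for the circadian clock). In cholesterol synthesis 1 of 19 rose, over all genes and adjusted over the list alone: the isomerase IDI1, with 0.21 ± 0.04. In cholesterol uptake, storage and efflux 2 of 18 rose and 1 fell, the same when adjusted over the list alone: MYLIP, which degrades the LDL receptor, with 0.86 ± 0.09, the HDL receptor SCARB1 with 0.18 ± 0.03 and the esterifying enzyme SOAT1 with -0.28 ± 0.06. IDI1 and MYLIP turned in sign without _x_at and _s_at probe sets. In the circadian clock 4 of 14 rose and 1 fell, and 5 and 5 when adjusted over the list alone, with BHLHE40 at 0.90 ± 0.05 and DBP at -0.49 ± 0.06. The other DBP probe set, not of the _s_at type, changed by -0.062. Calls of DBP and SCARB1 ended in some alternatives (limma adjusted p from 1.87e-07 to 0.885 and from 0.000179 to 0.142). In the cell cycle 1 of 20 rose, the inhibitor CDKN1A with 0.87 ± 0.05, while 1 rose and 5 fell when adjusted over the list alone, and the list passed downwards without DMSO replicate 1 or angiotensin II replicate 1 (adjusted p = 0.0486 and 0.0498, range 0.0267 to 0.467). Of 11 adrenal medulla markers 1 rose, over all genes and adjusted over the list alone: SCG2, a granule protein, with 0.58 ± 0.14. The SCG2 call ended without DMSO replicate 2 or 3 or angiotensin II replicate 1 or 3 (adjusted p = 0.0788, 0.0866, 0.0981 and 0.0860, range 0.00138 to 0.0981), and the SOAT1 call without DMSO replicate 1 or angiotensin II replicate 2 (0.0509 and 0.0591, range 0.00484 to 0.106). Of 14 fibroblast, endothelial and immune markers 0 changed by either adjustment (limma, 3 higher at an unadjusted p of 0.05). CETP itself was dim, at 3.89 ± 0.16 with DMSO, and its change of 0.07 ± 0.13 did not pass.

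Torcetrapib against DMSO addresses whether the CETP inhibitor acts on adrenal cells at all. NR4A2 rose 12.4-fold with torcetrapib, from 6.25 ± 0.25 (SD, n = 3) to 9.88 ± 0.13, more than any other gene. SIK1 rose 3.34-fold, the zinc finger gene ZNF331 2.78-fold, GEM 2.77-fold, NR4A3 2.75-fold and NR4A1 2.57-fold. NPAS4, the leading gene with angiotensin II, had a log2 change of 0.03 ± 0.14 with torcetrapib. HES1 showed the largest fall and ended 1.68-fold lower by its brightest probe set.

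With limma 117 genes rose and 112 fell with torcetrapib, 229 in all, and 2639 passed an unadjusted p of 0.05. Of the 229, 228 had treated arrays all on one side of the DMSO arrays, as did 16.5% of all genes, where chance gives 10%. Rises of at least 1.5-fold numbered 40 and falls 4. The count moved with single arrays: it was 917 without DMSO replicate 2, 94 without DMSO replicate 1, 105 without DMSO replicate 3, and 83, 92 and 84 without torcetrapib replicate 1, 2 or 3. The share that rose depended on the scaling, at 51.1% of 229, 66.9% of 118 with arrays centred on their medians and 33.4% of 518 with the values quantile normalised again. With the 5′ to 3′ index in the model, an alternative added after the data were seen, 76 genes passed, 71 of them higher, and 56 of these were among the 229. Across the 229 the median change with the index was 85.1% of that without it, and the median SE rose from 0.0633 to 0.0804.

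NR4A2 led the rises (log2 change 3.63 ± 0.10, adjusted p = 1.36e-11), followed by SIK1 (1.74 ± 0.09, adjusted p = 2.38e-08). ZNF331 rose by 1.47 ± 0.07, GEM by 1.47 ± 0.06, NR4A3 by 1.46 ± 0.05, NR4A1 by 1.36 ± 0.04, CCN1 by 1.28 ± 0.04, MITF by 1.21 ± 0.05, TRIB1 by 1.07 ± 0.06 and the linker histone H1-3 2.30-fold. All of these but H1-3 were called with the index in the model too, NR4A2 with a log2 change of 3.90 and SIK1 with 1.97. Without _x_at and _s_at probe sets the NR4A1 and SIK1 calls ended (log2 changes 0.115 and 0.314), that of HES1 ended with a turn in sign (0.0887, adjusted p = 0.817, range 8.66e-06 to 0.817), and NR4A2 had no value. A second _x_at probe set of NR4A1 changed by 0.89 with torcetrapib, and a second _s_at probe set of HES1 by -0.46. Among the falls, HES1 fell by 0.75, LINC02239 fell by 0.71, DUSP6 fell by 0.63, GATA3 fell by 0.61 and NDP, a ligand of WNT receptors, fell by 0.56 on the log2 scale. DAND5, TXNIP, SP6, KMT2B and TRIB2 had changes between -0.53 and -0.49. Of these 10 falls HES1, DUSP6 and TRIB2 were called with the index in the model, where their changes were -0.67, -0.49 and -0.45. Those that lost their calls were then at -0.60 in DAND5, -0.58 in NDP, -0.59 in LINC02239, -0.47 in TXNIP, -0.46 in GATA3, -0.40 in SP6 and -0.30 in KMT2B. LINC02239, NDP, DAND5, SP6 and KMT2B also lost their calls without single DMSO or torcetrapib arrays, LINC02239, NDP, SP6 and KMT2B without DMSO replicate 1 (adjusted p = 0.113, 0.0766, 0.0993 and 0.116) and DAND5 without DMSO replicate 3 (adjusted p = 0.069), against highest values over all their alternatives of 0.461, 0.200, 0.552, 0.670 and 0.104.

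Both lists that led with angiotensin II rose with torcetrapib as well. Of 23 immediate early transcription factors 14 rose, and 15 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.98e-33). Beyond the NR4A genes, FOS rose by 1.04, ATF3 by 0.91 ± 0.07 and KLF6 by 0.51, whereas FOSB had a change of 0.50 that did not pass (adjusted p = 0.064). Of 15 cAMP and CREB targets 8 rose, and 11 when adjusted over the list alone (camera adjusted p = 8.52e-38). They were the 3 NR4A genes, GEM, SIK1, DUSP1 (0.88 ± 0.05), PDE4B (0.57) and CREM (0.28). With the index in the model these lists had adjusted p = 3.49e-42 and 1.33e-47 (ranges over their alternatives 3.49e-42 to 0.00700 and 1.33e-47 to 0.00434). Regulators of MAP kinase and G protein feedback went both ways, with 4 of 19 higher and 3 lower, and 5 and 5 when adjusted over the list alone. DUSP1 and SPRY2 (0.60) rose and DUSP6 fell, and the list did not pass (camera adjusted p = 0.43), its median of -0.05 differing in sign from its mean of 0.02.

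Of 15 steroidogenesis genes 1 rose with torcetrapib, over all genes and adjusted over the list alone. FDX1 rose 1.29-fold (log2 change 0.37 ± 0.06, adjusted p = 0.00717). That call ended without torcetrapib replicate 2 (adjusted p = 0.0567), with the mean of its probe sets (0.0771), without the intensity trend (0.146) and with the index in the model, where its change was 0.178 (adjusted p = 0.309, range 0.000165 to 0.309). STAR had a change of 0.08 with a 95% interval from -0.01 to 0.16, CYP11B2 of 0.14 with an interval from -0.18 to 0.47 and MC2R of 0.21 with an interval from -0.01 to 0.42. CYP11B1 (-0.14, interval -0.33 to 0.06), CYP11A1 (-0.08, -0.17 to 0.01), CYP17A1 (-0.12, -0.24 to 0.01) and HSD3B2 (-0.03, -0.16 to 0.11) did not pass either. The list did not pass (camera adjusted p = 0.345), and its median of -0.03 differed in sign from its mean of 0.02 and from the test's upward direction.

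Among RAAS components 0 of 11 changed with torcetrapib by either adjustment (limma, 0 at an unadjusted p of 0.05), and AGTR1 had a change of -0.07 ± 0.04. Of 29 calcium signalling genes, pumps and channels 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0818, and 0.0152 without DMSO replicate 2, range 0.0152 to 0.633). It was KCNJ5, a potassium channel of the zona glomerulosa, which ended 1.21-fold lower (log2 change -0.27 ± 0.05, adjusted p = 0.015). That call ended without DMSO replicate 1 or 3 or any of the torcetrapib arrays (adjusted p from 0.0709 to 0.0848), with the index in the model (0.484) and with the mean of its probe sets, where the sign turned, and its adjusted p ranged from 0.000883 to 0.997. RCAN1 had a change of 0.02 ± 0.06 by its brightest probe set. A second RCAN1 probe set rose by 0.66 with torcetrapib (limma over all probe sets, adjusted p = 0.0496). Of 16 zona glomerulosa and WNT markers 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0327). It was DAB2, with -0.32 ± 0.03 (adjusted p = 9.30e-05), a gene still called with the index in the model and not with the mean of its probe sets (adjusted p = 0.191, range 8.69e-06 to 0.191). The list lost its call with an estimated correlation (adjusted p = 0.13), without DMSO replicate 2 (0.168) and without torcetrapib replicate 1 (0.0762), with a range over the alternatives from 0.000853 to 0.992.

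For stress lists the camera calls with torcetrapib, all upwards, depended on the correlation assumed between genes, and each had 1 member past the test over all genes. For ER stress (HERPUD1, 0.17 ± 0.03, of 20 genes) the adjusted p was 0.000193, for heat shock (DNAJA1, 0.23 ± 0.05, of 9) 0.0238 and for oxidative stress and xenobiotic response (TIPARP, 0.84 ± 0.06, of 18) 0.00111. The calls were lost with an estimated correlation, at adjusted p = 0.407, 0.136 and 0.13 (ranges over the alternatives 2.19e-05 to 0.407, 0.000219 to 0.194 and 0.00046 to 0.13). Adjusted over the list alone, 4 rose and 1 fell, 2 rose and 2 rose. With the index in the model the adjusted p were 0.00805, 0.194 and 0.0313. Of the 3 genes only TIPARP was called with the index. HERPUD1 and DNAJA1 lost their calls without DMSO replicate 1 (adjusted p = 0.137 and 0.135), DMSO replicate 3 (0.0966 and 0.102) or any 1 of the torcetrapib arrays (ranges over the alternatives 0.00549 to 0.934 and 0.00272 to 0.998), and HERPUD1 turned in sign without _x_at and _s_at probe sets.

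In cholesterol synthesis 0 of 19 genes rose and 3 fell with torcetrapib, and 6 fell when adjusted over the list alone (camera adjusted p = 0.0756). LSS, INSIG1 and MSMO1 had changes of -0.20 ± 0.04, -0.18 ± 0.04 and -0.18 ± 0.04, and lost their calls without DMSO replicate 1 (adjusted p = 0.153, 0.165 and 0.194), DMSO replicate 3 (0.102, 0.0690 and 0.166) or any 1 of the torcetrapib arrays, and with the index in the model (changes of -0.17, -0.19 and -0.15, ranges over the alternatives 0.005 to 0.989, 0.00362 to 0.871 and 0.00474 to 0.675). The list as a whole passed downwards without DMSO replicate 1 (adjusted p = 0.00401) and with the index (9.23e-05, range 9.23e-05 to 0.674). In cholesterol uptake, storage and efflux 0 of 18 changed by either adjustment (limma, 1 higher and 1 lower at an unadjusted p of 0.05), and CETP had a change of 0.04 ± 0.13. Of 23 secreted growth factors and cytokines 1 rose, CCN1, and 2 when adjusted over the list alone (camera adjusted p = 0.0659, and 0.0451 without angiotensin II replicate 2, 0.0346 without torcetrapib replicate 1 and 0.032 with the index in the model, range 0.032 to 0.465), while HBEGF had a change of 0.13 ± 0.09 and LIF of -0.06 ± 0.09. In the circadian clock 0 of 14 changed over all genes (limma, 0 higher and 5 lower at an unadjusted p of 0.05) and 3 fell when adjusted over the list alone (camera adjusted p = 0.0781). In the cell cycle 0 of 20 changed by either adjustment (limma, 5 lower at an unadjusted p of 0.05). The same held for 0 of 11 adrenal medulla markers and 0 of 14 fibroblast, endothelial and immune markers (limma, 0 of each at an unadjusted p of 0.05), with camera adjusted p = 0.397, 0.496 and 0.615 for these last 3 lists. The last 2 lists had medians of 0.03 and 0.01 and means of -0.00 and -0.01.

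Torcetrapib against angiotensin II compares both agents directly, at the same labelled dose and time. NPAS4 was 34.8-fold lower with torcetrapib than with angiotensin II, FOSB 10.3-fold, NFKBIZ 7.91-fold, ATF3 7.24-fold and GEM 6.67-fold. NR4A2 differed less, being 2.33-fold lower. Higher with torcetrapib were GNL3L (3.25-fold), GTF2I (2.98-fold), H1-3 (2.73-fold), ZNF658 (2.71-fold) and GTF2H2B (2.64-fold). ZNF658 and GTF2H2B had fallen with angiotensin II.

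By limma 911 genes were higher and 1321 lower with torcetrapib, 2232 in all, a balance that turned with the mean of probe sets (1329 higher, 979 lower) and over all probe sets (3139 higher, 1876 lower). Of all genes 4902 passed an unadjusted p of 0.05, and 2213 of the 2232 had the arrays of both groups apart, as did 28.6% of all genes, where chance gives 10%. The log2 differences of NPAS4 (-5.12 ± 0.14), FOSB (-3.36 ± 0.12), NFKBIZ (-2.98 ± 0.08), ATF3 (-2.86 ± 0.07) and GEM (-2.74 ± 0.06) were past the threshold with the index in the model too. With that index the count was 280, of which 258 were among the 2232, and GNL3L, GTF2I, H1-3 and GTF2H2B lost their calls. Of these, GNL3L was then at 0.191 and GTF2I at 0.0696, while H1-3 was at 1.22 (1.45 without the index) and GTF2H2B at 1.17 (1.40 without it). Over the 2232 genes the median difference with the index was 76.7% of that without it, and over all genes the median SE rose from 0.0883 to 0.157. GNL3L and GTF2I also varied widely among the DMSO arrays (SD 1.01 and 0.90). Of 731 genes with at least 2 called probe sets, 115 had called probe sets in opposite directions, and the count was 1425, 1486 and 1351 without torcetrapib replicate 1, 2 or 3.

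The lists that angiotensin II had raised most were lower with torcetrapib. Of 23 immediate early transcription factors 22 were lower, over all genes and adjusted over the list alone (camera adjusted p = 1.89e-47), as were 10 of 15 cAMP and CREB targets by both adjustments (3.20e-15). NR4A1 differed by -1.37 ± 0.04, NR4A3 by -1.51 ± 0.05 and SIK1 by -1.06 ± 0.09. Of 19 regulators of MAP kinase and G protein feedback 1 was higher, DUSP6 with 1.12 ± 0.06, and 10 were lower, or 1 and 11 when adjusted over the list alone (camera adjusted p = 5.66e-10). Of 23 secreted factors 12 were lower, and 14 when adjusted over the list alone (camera adjusted p = 1.71e-10), with HBEGF and LIF each at -2.45 ± 0.09. With the index in the model these 4 lists passed as well, as they did with an estimated correlation (camera adjusted p from 0.00434 to 0.0299). The NR4A1 call ended without _x_at and _s_at probe sets (adjusted p = 0.222, range 1.36e-14 to 0.222), while a second _x_at probe set differed by -1.34.

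Of 15 steroidogenesis genes 4 were lower with torcetrapib than with angiotensin II, and 2 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.288, and 0.0119 downwards with the index in the model, range 0.0119 to 0.620). FDX1 differed by -0.29 ± 0.06 (adjusted p = 0.00605, range over its alternatives 7.94e-05 to 0.0586), the reductase POR by -0.24 ± 0.05 (0.00508), CYP17A1 by -0.20 ± 0.06 (0.0395) and STAR by -0.13 ± 0.04 (0.0423). The STAR and CYP17A1 calls ended without any of the torcetrapib arrays (STAR adjusted p from 0.0862 to 0.153, CYP17A1 from 0.0655 to 0.171, ranges over all alternatives 0.00205 to 0.209 and 0.016 to 0.693), and that of POR with the index in the model (range 0.000192 to 0.573). CYP11B2 differed by -0.11 with a 95% interval from -0.43 to 0.21. Of 11 RAAS components 2 were higher and 1 lower, by both adjustments (camera adjusted p = 0.163), with AGTR1 at 0.24 ± 0.04, which lost its call with the index in the model. Of 29 calcium signalling genes 1 was higher and 4 were lower, or 1 and 6 when adjusted over the list alone (camera adjusted p = 0.033), RCAN1 with -0.73 ± 0.06 and NFATC2 with -0.87 ± 0.09. By a second RCAN1 probe set the difference was 0.19 (limma over all probe sets, adjusted p = 0.43). The calcium signalling list lost its call with an estimated correlation (adjusted p = 0.529), without angiotensin II replicate 3 (0.0874), without torcetrapib replicate 1 (0.0521) and with the index (0.357), over a range from 0.0164 to 0.964.

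ER stress genes were higher in 2 and lower in 8 of 20 cases, or 2 and 9 when adjusted over the list alone (camera adjusted p = 0.00111, and adjusted p = 0.465 with an estimated correlation, range 1.63e-06 to 0.465). PPP1R15A differed by -1.59 ± 0.07 and DDIT3 by -0.76 ± 0.06. Of 18 oxidative stress and xenobiotic genes 1 was higher and 6 lower by both adjustments (camera adjusted p = 0.00415, and adjusted p = 0.168 with an estimated correlation, range 0.00012 to 0.168), TIPARP with -1.12 ± 0.06. Of 9 heat shock genes 2 were lower by both adjustments (camera adjusted p = 0.599, and 0.0339 with the index in the model, range 0.0130 to 0.921), among them DNAJB1 with -0.79 ± 0.06. Zona glomerulosa and WNT markers were higher in 2 and lower in 1 of 16 cases by both adjustments (camera adjusted p = 0.0659), and DAB2 differed by -0.00 ± 0.03, or by 0.270 with the mean of its probe sets. In cholesterol synthesis 1 of 19 was higher and 6 lower, or 2 and 7 when adjusted over the list alone (camera adjusted p = 0.599, and 0.0156 with the index in the model, range 0.0156 to 0.840), and in cholesterol uptake, storage and efflux 1 of 18 was higher and 2 lower by both adjustments (0.241), SCARB1 with -0.29 ± 0.03. In the circadian clock 2 of 14 were higher and 3 lower, or 2 and 5 when adjusted over the list alone (0.241), BHLHE40 with -0.88 ± 0.05. In the cell cycle 2 of 20 were higher and 2 lower by both adjustments (0.287), CDKN1A with -0.79 ± 0.05, and the median of 0.05 differed in sign from the mean of -0.01. SCG2 was the 1 of 11 medulla markers that was lower (camera adjusted p = 0.869, upwards against a median of -0.02), and COL3A1 the 1 of 14 fibroblast, endothelial and immune markers (0.381), by both adjustments. Both calls ended without angiotensin II replicate 1 (adjusted p = 0.144 and 0.128) or torcetrapib replicate 1 (0.0823 and 0.122), with ranges over the alternatives from 0.000433 to 0.896 and from 0.000163 to 0.563, and that of SCG2 also without DMSO replicate 3, angiotensin II replicate 3 or torcetrapib replicate 2, that of COL3A1 also without torcetrapib replicate 3.

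The torcetrapib and angiotensin II responses overlapped in the genes that rose and in those that fell. At an unadjusted limma p under 0.05 in both, 264 genes were higher in both and 330 lower in both. Genes higher in both comparisons numbered 70, where independent lists of 665 and 117 would share 3.93, and genes lower in both 28, where 3.09 would be shared. None rose with angiotensin II and fell with torcetrapib (limma, 87 at unadjusted p under 0.05 in both), and 3 did the opposite (89 unadjusted): DNAJB14, TMEM165 and ATG12, named here after their values were seen, none of them called with the index in the model, where their torcetrapib changes were 0.40 (0.54 without it), 0.14 (0.43) and 0.24 (0.32). Across all genes, which are not independent replicates, the log2 changes correlated with r = 0.334 and rho = 0.202, where 100 simulations of unchanged groups sharing the 3 DMSO arrays gave means of 0.5002 and 0.4741. The covariance was 0.00957 against a simulated mean of 0.00418. In the same simulations a mean of 0.02 genes were higher in both, and 0.02 lower in both, with at most 1 of each. They hold no changed genes, and 3 DMSO arrays cannot be split into parts of 2 each, so how much the shared controls add to the overlap of changed genes was not measured.

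Among the 1210 genes called with angiotensin II, the torcetrapib change had a slope of 22.3% of the angiotensin II change. The direct contrast called 908 of them shifted against the direction of the angiotensin II change, 1 shifted further along it and 301 not different. It reuses the angiotensin II arrays that chose the 1210 genes, which favours shifts against that direction. With the 5′ to 3′ index in the model this contrast called 280 genes in all, against 2232 without it, so most of the 908 were not called there. The slope in that model was 0.253, over the genes it called with angiotensin II. The 908 hold weaker changes as well as genes that turned in sign, such as DNAJB14, at -0.34 with angiotensin II and 0.54 with torcetrapib. Of the 1210 genes 875 had the same sign with both agents. Of the 113 genes that rose at least 2-fold with angiotensin II, 112 were weaker with torcetrapib and ZNF331 was stronger, at 2.78-fold against 2.33-fold (log2 difference 0.25 ± 0.07, adjusted p = 0.0283). A second ZNF331 probe set rose with both agents and differed by -0.13 between them (adjusted p = 0.654), so the greater rise with torcetrapib rests on 1 of 2 probe sets. The share of the log2 change kept with torcetrapib differed widely, between 120% for ZNF331 and -27.8% for the transcription factor SALL1, which was dim at 4.48 with DMSO. It was 74.9% for NR4A2, 66.2% for DUSP1, 62.1% for SIK1 and 55.3% for CCN1, and 5.10% for HBEGF, 0.57% for NPAS4, -2.44% for LIF and -15.4% for KLF10. These shares can depend on the probe set. With angiotensin II and torcetrapib, NR4A3 changed by 2.97 and 1.46 by its brightest probe set and by 2.55 and 2.20 by another. DUSP1 changed by 1.33 and 0.88, and by 0.23 and 0.70 by another. The NR4A2 probe sets were alike, from 4.85 to 5.22 and from 3.63 to 3.90. Of 128 genes called with torcetrapib and not with angiotensin II, 96 differed in the same direction in the direct contrast. That contrast reuses the arrays that chose these genes, so the agreement is not independent evidence. With the index in the model 46 of the 98 genes called in one direction with both agents stayed called with torcetrapib, and 10 of the 128, among them ZBED6, LMNB1, MLEC and GLG1, named here after their values were seen. The median change with the index was 102% of that without it for the 98 and 74.4% for the 128, while the median SE rose from 0.0622 to 0.0827 and from 0.0640 to 0.0793.

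**Figure D3:**
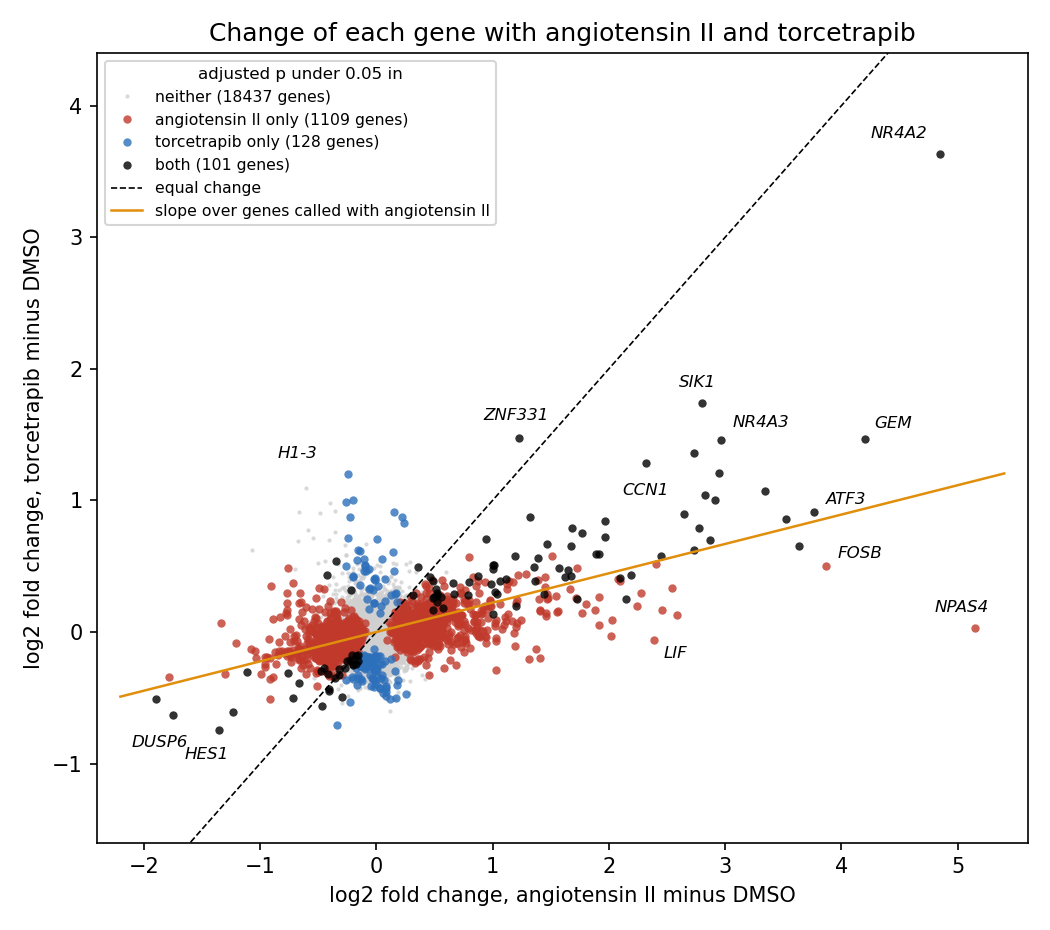
Log2 fold change of each of 19775 genes with torcetrapib (vertical axis) against that with angiotensin II (horizontal axis), both against DMSO, coloured by where the gene passed an adjusted p of 0.05, with a dashed line of equal change and a solid line at the slope over the genes called with angiotensin II. Most genes called with angiotensin II lie closer to 0 on the vertical axis, with NR4A2 at 4.85 and 3.63 and NPAS4 at 5.15 and 0.03.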

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

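The 5′ to 3′ index as a covariate was chosen after results were seen, while every other alternative here was chosen before the data were examined. No paired analysis was possible because replicate numbers only follow the order of accessions and pair nothing between groups. For results that changed, the cause was not tested.

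With angiotensin II against DMSO, 1210 genes changed. The count was 2712 with array weights, 330 at 1.5-fold or more, 767 at an adjusted p of 0.01, 1081 with the index and from 956 to 1171 with 1 array left out. Array weights put angiotensin II replicate 1 at 6.15, against 0.448 and 0.480 for replicates 2 and 3. Weighted counts of comparisons with angiotensin II therefore rest largely on 1 array of that group. With torcetrapib against DMSO, 229 genes changed. The count was 50 without the intensity trend, 403 with only genes above the median level, 118 with arrays centred on their median, 518 quantile normalised again, 108 with the mean of probe sets, 136 without _x_at and _s_at probe sets, 362 over all probe sets, 145 with only the 2 groups, 1272 with array weights, 44 at 1.5-fold or more, 78 at an adjusted p of 0.01, 76 with the index and from 83 to 917 with 1 array left out. Between torcetrapib and angiotensin II, 2232 genes differed. The count was 5015 over all probe sets, 6216 with array weights, 349 at 1.5-fold or more, 1104 at an adjusted p of 0.01, 280 with the index and from 1351 to 2653 with 1 array left out. Its share of higher genes was 40.8%, but 57.6% of 2308 with the mean of probe sets and 62.6% over all probe sets.

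Of 51 list tests 21 passed, against 12 with an estimated correlation, 23 with fry by direction, 43 with fry in either direction, 25 with the index and 20 to 23 with 1 array left out. The correlation of both responses, r = 0.334, was 0.375 with only genes above the median level, 0.246 with the mean of probe sets, 0.298 with the index, 0.597 over genes called in at least 1 comparison and 0.281 to 0.391 with 1 array left out. The slope of 0.223 was 0.242 with only genes above the median level, 0.236 with the mean of probe sets, 0.253 with the index and 0.212 to 0.243 with 1 array left out.

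Sign turns are listed here only for named genes past the threshold before the alternative or under it; others, past it in neither, also turned and are left out. Most of those listed came without _x_at and _s_at probe sets, where another probe set stands for the gene. With angiotensin II these were CXCL2 (-0.0235), HERPUD1 (-0.0941), HES1 (0.0675), IDI1 (-0.338) and MYLIP (-0.0629), with torcetrapib HERPUD1 (-0.130) and HES1 (0.0887), and between the treatments CXCL2 (0.140), IDI1 (0.285), MYLIP (0.00210), DBP (-0.0264) and DNAJA1 (-0.167). With the mean of probe sets, of such genes, KCNJ5 turned with torcetrapib (0.00112), and KCNJ5 (0.305), BHLHE41 (0.0355) and DAB2 (0.270) between the treatments. With the index no such gene turned. For angiotensin II, torcetrapib and their contrast, 58, 123 and 121 other alternatives of named genes were weaker and 23, 26 and 9 stronger.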

Other observations

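The splits of arrays were written down before the results were seen, while the tests of the RNA-quality index, of the signal floor and of the CREB list were chosen after them. Regrouping the 6 arrays of a comparison gives 10 splits into 3 and 3, too few for a share under 0.05. In each comparison only 1 split, the real one, gave as many genes (1210, 229 and 2232 for angiotensin II, torcetrapib and their contrast), 1 of 10 each, and the highest other split gave 0 genes by limma (2383, 1635 and 1626 at an unadjusted p of 0.05, against 3259, 2639 and 4902). Every other split mixes both treatments in each part, so any treatment effect widens its errors and a low count is built in. These counts therefore say nothing about chance.

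The first pattern is the torcetrapib response itself, of which RNA quality is a technical explanation. Of the 98 genes called in one direction with both treatments, 39.8% leaned with the 5′ to 3′ index in the direction of their change within the DMSO and angiotensin II arrays. With the index in the model their median change was 102% of that without it, with NR4A2 at 3.90 and SIK1 at 1.97. Against DMSO the index itself moved by -0.12 with angiotensin II and by 0.26 with torcetrapib. Choosing genes that moved alike with both already disfavours genes that follow the index, so their low share is not independent evidence against RNA quality. Of the 128 genes called with torcetrapib and not with angiotensin II 83.6% leaned that way, against 59.8% of uncalled genes, so RNA quality may account for part of their change. The lean predicts 25.7% of their change, the index left a median of 74.4%, and the median SE rose from 0.0640 to 0.0793. Both percentages rest on the spread of the index within groups, which lay mostly among the 3 DMSO arrays. Its SD was 0.22 with DMSO, 0.02 with angiotensin II and 0.03 with torcetrapib. These percentages therefore cannot bound the part due to RNA quality. Between torcetrapib and angiotensin II, 15.7% of genes with at least 2 called probe sets had called probe sets in opposite directions, as differing 5′ to 3′ signal would give. Against DMSO this held for 0 of 39 such genes with torcetrapib and for 2 of 244 with angiotensin II. The torcetrapib response against DMSO thus showed no such sign, among only 39 genes.

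The second pattern is that torcetrapib kept unequal shares of the angiotensin II response. A signal floor of dim probe sets could give unequal shares, yet 68.3% of induced genes with a DMSO level of at least 8 departed from the common share. Without the index 48.7% of the 113 induced genes departed, 22 above and 33 below that share, and with the index in the model 31.9% departed, 22 above and 14 below, more than the 10% written as the limit for RNA quality as the sole cause. The 33 genes below had a median departure of -0.31 without and -0.27 with the index, while their median SE rose from 0.0777 to 0.121, so wider errors may have ended many of these calls. A signal floor alone does not account for the spread of shares. For RNA quality the test cannot decide, because the index was fitted mostly on the spread among the DMSO arrays. Its SD was 0.22 there, against 0.02 with angiotensin II and 0.03 with torcetrapib. The correction may therefore be too small, and departures past the 10% limit could remain even if RNA quality were the sole cause. Differences between probe sets of the same gene could add to the spread of shares and were not tested.

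The third pattern is that induced CREB-list genes kept a larger share than the other immediate early genes, with medians of 49.2% (n = 9) and 19.6% (n = 14). NR4A1, NR4A2, NR4A3 and FOSB belong to both fixed lists and were counted with the CREB list only. Shares can depend on the probe set, as given above for NR4A3 and DUSP1, both in the CREB list. A two-sided permutation test with 100000 resamples gave p = 0.0114, and a second run without the NR4A genes gave 37.8% (n = 6) with a permutation p = 0.039. Against all 27 other induced genes of the fixed lists, added last, with a median of 14.3%, the permutation p was 0.0038. Single shares overlapped, from 13.0% to 74.9% in the CREB list and from -15.4% to 50.6% in the other immediate early genes. Whether torcetrapib acts more on a cAMP or CREB route than on a calcium route was not tested. The shares of a list cannot tell these routes apart, since no array blocked either of them. All 3 runs were chosen after the shares were seen, and the genes are not independent, so these p-values are too small by an unknown amount.

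Measuring FDX1 and the genes called with torcetrapib alone by quantitative PCR, in RNA of matched quality, would separate treatment from RNA quality for these. The log2 change of FDX1 with torcetrapib was 0.37, and 0.178 with the index in the model. Adding a calcium chelator or a protein kinase A inhibitor would test whether either route carries the third pattern.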
